A study of Mus musculus with 12 samples.

How the data were processed

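RNA was measured in liver tissue that, per the labels, was taken by laser capture from zone 1 (around the portal tracts) and zone 3 (around the central veins) of untreated male and female C3H/HeNCrlBR mice. The 12 samples fall into 4 groups of 3 arrays each: male zone 1, male zone 3, female zone 1 and female zone 3. Per the labels, RNA was isolated with an Arcturus PicoPure kit, amplified with the NuGEN Ovation Pico WTA system, labelled with Cy3 and hybridised to an Agilent single-colour mouse array, 1 array per sample. The labels say that each mouse gave tissue from both zones, but no label ties a zone 1 capture to a zone 3 capture of the same animal. Each group's 3 arrays are taken here to come from 3 different mice, which the replicate numbers alone do not show. No block for mouse was therefore fitted in the main model. The p-values for zone, for sex averaged over both zones and for the difference of the zone effect between the sexes ignore that both zones came from the same mice.

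The deposited scanner files hold, per the file headers, spot intensity on a linear scale from Agilent Feature Extraction 9.5.3.1 (the submitters' notes name version 9.5). The processed signal in them is, per the file headers, an intensity after subtraction of background and of a spatial trend and after multiplicative detrending within the array, with surrogate values for spots near background. The mean signal and the background median are, per the file headers, the mean pixel intensity of a spot and the median intensity of its local background. The same files give flags of other kinds, per the file headers: whether a spot is well above background, saturated or an outlier. The deposited value table holds the same unit, intensity. Its values equalled the processed signal at all 45018 spots in 12 of 12 arrays, were not centred (medians 33 to 66.2) and had not been scaled between arrays.

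The arrays were hybridised on 3 slides. Slide 1 held the 3 male zone 3 arrays and male zone 1 replicate 1. Slide 2 held male zone 1 replicates 2 and 3 and female zone 3 replicates 1 and 2. Slide 3 held female zone 3 replicate 3 and the 3 female zone 1 arrays. Each slide was scanned as 1 batch, so slide and scan cannot be separated. A fit with slide as a fixed block could be estimated because slides 1 and 3 held both zones of 1 sex and slide 2 linked the sexes, and its values are given beside the others. No slide held both sexes of 1 zone, so within-slide values exist for zone in males (slide 1) and in females (slide 3) but not for sex.

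Control spots (1639 per array) and outlier spots were left out, the remaining spots of a probe were averaged, and the processed signal was taken to log2 minus the array's 75th percentile. A probe was kept if it was well above background on all 3 arrays of at least 1 group, which 28647 of 41174 probes were. Gene names came from the RefSeq identifiers of the probes and a table of current symbols (22951 probes), from symbols in the files (6659), from synonyms (3109) or from names as the files gave them (1915). The other 6540 probes had no gene name and were not tested. Each gene was represented by its brightest kept probe, which gave 16270 genes tested of 21228 on the array, with 53 missing values. Coordinates are those of the probes in the files, on build mm7 (NCBI35), and probes were not placed on a current genome here. Of the genes named by the rule below, 107 had several kept probes and 17 had probes of opposite sign in at least 1 comparison. Probes for families of close copies (Mup, Cyp2a, Cyp2c, Cyp3a41, Cyp4a, Hba, Hbb) may read more than 1 member, so values of such genes are uncertain between copies.

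A limma model (version 3.58.1, R 4.3.3, with the packages data.table, version 1.17.8, and jsonlite, version 2.0.0, to read the files) with a mean for each of the 4 groups was fitted to all arrays at once, with 8 residual and 3.58 prior degrees of freedom. The comparisons were zone 3 minus zone 1 as the mean of both sexes, in males and in females, male minus female in zone 1 and in zone 3, and the zone difference in males minus that in females, called sex by zone below. A gene is called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. All p-values are two-sided. Errors on log2 differences are standard errors from the fit, and errors on levels are standard deviations over arrays. A fold is the back-transformed size of a log2 difference, with its direction in the text. Where a group on the lower side was not well above background on any of its arrays, its value on each array was raised to the array's lowest signal well above background, and the fold is written as at least that many fold. Where a group on the higher side was not well above background either, no fold is given. Where some arrays of a group measured a gene and others did not, their number is given, and the fold is the lower bound with the other arrays raised in the same way.

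Before the data were examined, 38 gene lists with 664 members, of which 628 were tested, were fixed, as were the comparisons, the filters, most alternatives and the rule for named genes. Lists were tested with camera of limma at its preset inter-gene correlation of 0.01, adjusted over the lists within a comparison, and again with the correlation estimated per list. For each list the numbers of members called are given over all genes and adjusted over the list alone. Named genes are, for each comparison, the 10 with the largest positive and the 10 with the largest negative difference among called genes whose groups do not overlap (no such condition for sex by zone), up to 4 members with the smallest p of each list that was called or holds a called member, and X and Y chromosome genes that check the sex labels. Some genes that the rule names are not reported. Named genes were followed under the alternatives in each comparison that called them, and the 12 sex by zone genes in every comparison; that restriction was set after the first values under the alternatives were seen, and no value is printed for a named gene outside it.

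The alternatives were normexp background correction with offset 50 on the mean signal and background median, quantile normalization, centring on the median, the deposited values without scaling, no filter, a filter for probes well above background on all arrays, the mean of the kept probes, slide as a fixed or random block, trend and robust variance estimation, array weights, a fit of only the arrays of a comparison, a replicate block, and leaving out each array in turn. Leaving out both male zone 3 replicate 1 and female zone 3 replicate 3, and raising every value to at least the array's lowest signal well above background, were added after seeing the data. Other arrays lay about as far from their groups on a principal component as female zone 3 replicate 3 did and were left out only 1 at a time. The normexp offset is added to the intensity of every spot, so it shrinks log2 differences of dim genes by construction. A count is called moved when it changes by more than 1.5 times, and a correlation when it changes by more than 0.1. The pipeline was tested on simulated data drawn from each gene's mean and residual standard deviation with known differences added: larger differences were recovered more often than smaller ones, and sex by zone differences less often than the same differences between groups. The share of spots well above background ranged from 61.9% to 74.2% over arrays and the 75th percentile of intensity from 189.6 to 319.2. For arrays there is no count from which to derive an interval, and the number of arrays limits the precision.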

Results

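Gene expression was measured on 12 arrays of laser-captured mouse liver, 3 arrays in each of the groups male zone 1, male zone 3, female zone 1 and female zone 3. The replicate arrays of a group correlated at r = 0.956 to 0.981 across genes, which are not independent replicates. The first principal component, with 40.6% of the variance, separated all zone 3 arrays (-61.2 to -24.2) from all zone 1 arrays (37.2 to 57.9). The second, with 16.1%, separated all male arrays (21.7 to 40.9) from all female arrays (-59 to -18.7). Xist, transcribed from the inactive X chromosome, was at 5.28 ± 0.16 (SD, n = 3) in female zone 3 and -4.35 ± 0.41 in male zone 3, where 2 of 3 arrays measured it, in log2 units relative to the array's 75th percentile. Male zone 3 replicate 1 stood apart from the other male zone 3 arrays on the third component (58.4 against 0.7 and -11.3), and female zone 3 replicate 3 from the other female zone 3 arrays on the second (-59 against -19.8 and -32.5). On the third component female zone 3 replicate 1 (-38.5 against -2.3 and -7.9) and female zone 1 replicate 3 (38.5 against -8 and 11.9) also lay apart from their groups, less far than male zone 3 replicate 1.

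Centring arrays on the median instead of the 75th percentile moved the median difference of all genes from 0.00 to 0.14 for zone in both sexes, from 0.03 to 0.19 for zone in males, from -0.03 to 0.08 for zone in females, from -0.07 to 0.06 for sex in zone 1 and from 0.00 to 0.18 for sex in zone 3. With normexp it became 0.11 for zone in females, 0.13 for sex in each zone and -0.09 for sex by zone, which stood at 0.07. Without scaling it became -0.25 for zone in both sexes, -0.50 for zone in females, -0.41 and 0.11 for sex in zones 1 and 3 and 0.51 for sex by zone. All differences below are relative to the 75th percentile.

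The first comparison, named zone in both sexes, asks which genes differ between zone 3 and zone 1 in the mean of both sexes. A gene that differs in 1 sex alone can be called in it. Slc1a2, a glutamate transporter, was higher in zone 3 by a log2 difference of 8.48 ± 0.35 (SE, 6 arrays per zone; at least 340-fold, adjusted p = 1.89e-08), at 4.64 ± 0.05 (SD, n = 3) in male zone 3 against -3.76 ± 1.37 in male zone 1, where 2 of 3 arrays measured it. Glul, which makes glutamine from glutamate and ammonia, was higher by 5.66 ± 0.26 (50.5-fold), Oat, ornithine aminotransferase, by 6.54 ± 0.28 (93.0-fold) and Cyp2e1, an ethanol-oxidising enzyme, by 5.68 ± 0.21 (51.1-fold). Spp1, which encodes osteopontin, was lower in zone 3 by -8.56 ± 0.50 (at least 289-fold, adjusted p = 3.03e-07) and was measured on 2 of 3 zone 3 arrays of each sex. Cyp2f2 was lower by -6.15 ± 0.26 (70.8-fold), Gls2, the liver glutaminase, by -5.32 ± 0.17 (40.0-fold) and Hal, which opens histidine breakdown, by -4.53 ± 0.19 (23.1-fold).

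All 30 tested members of the pericentral hepatocyte list were higher in zone 3, with a median of 3.04 (adjusted p = 2.25e-47; 30 adjusted over the list alone), among them Lhpp (at least 91.3-fold, measured on 2 of 3 male zone 1 arrays) and Cyp1a2 (18.0-fold). All 16 tested beta-catenin targets rose as well, with a median of 4.34, or 3.81 with 3 dim members at their bound (adjusted p = 5.73e-30; 16 adjusted over the list alone). Axin2, a feedback inhibitor of Wnt signalling, was at least 12.1-fold higher, the transcription factor Tbx3 at least 27.6-fold and Lect2 44.1-fold. Of 32 tested periportal hepatocyte genes 25 fell and 1 rose (the same counts adjusted over the list alone), with a median of -2.23 (adjusted p = 4.23e-26). Etnppl was 60.3-fold lower, Hsd17b6 23.1-fold, Sds, serine dehydratase, 14.0-fold, and the cell adhesion gene Cdh1 at least 22.2-fold.

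Markers of other cell types moved with zone. Of 17 bile duct markers 13 fell in zone 3 and none rose (14 down adjusted over the list alone; median -2.71, adjusted p = 2.04e-15), with Krt19 (measured on 1 of 3 female and 0 of 3 male zone 3 arrays) at least 25.2-fold and Cd24a 18.8-fold lower. Portal endothelium markers fell in 7 of 8 cases (7 adjusted over the list alone; median -1.78, adjusted p = 7.44e-09), among them Efnb2 at 9.22-fold and Hey1 at 4.52-fold. Fibroblast and smooth muscle markers fell in 10 of 20 cases and rose in 1 (13 and 1 adjusted over the list alone; median -0.83, adjusted p = 3.36e-07), with the matrix genes Mgp 9.65-fold and Fbln1 4.90-fold lower. Central vein endothelium markers rose in 6 of 7 cases (6 adjusted over the list alone; median 1.13, adjusted p = 1.81e-06). The Wnt ligand Wnt2 was at least 15.0-fold higher and Rspo3, which amplifies Wnt signalling, at least 21.7-fold, measured on 2 of 3 arrays in each zone 1 group. Of 14 lymphocyte and antigen presentation genes 3 fell (3 adjusted over the list alone), the class II genes H2-Aa, H2-Eb1 and Cd74, with folds of 4.79, 3.55 and 4.44 (list median -0.31, adjusted p = 0.00246, but adjusted p = 0.0596 with an estimated correlation).

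Xenobiotic phase I genes rose in 25 of 39 cases and fell in 4 (27 and 4 adjusted over the list alone; median 0.96, adjusted p = 2.04e-15). Conjugation and glutathione genes rose in 19 of 34 and fell in 2 (22 and 3 adjusted over the list alone; median 0.65, adjusted p = 6.2e-10), with Gstm2 24.4-fold and Gstm3 8.27-fold higher. Bile acid genes rose in 12 of 23 and fell in 1 (16 and 1 adjusted over the list alone; median 0.82, adjusted p = 6.2e-10). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, rose 22.4-fold (log2 4.49 ± 0.32) and the transporter Slco1b2 5.40-fold. Fatty acid oxidation genes rose in 9 of 25 cases (12 up and 1 down adjusted over the list alone; median 0.42, adjusted p = 4.39e-08), with Acot1 15.4-fold and Cyp4a14 9.79-fold higher. The male-biased liver list rose in 10 of 23 and fell in 2 cases (14 and 2 adjusted over the list alone; median 0.49, adjusted p = 1.75e-06). These lists and the cell type lists above, except the lymphocyte list, were called with an estimated correlation as well. Some members also stand in another list: 14 of 41 for xenobiotic, 7 of 37 for conjugation and 6 of 23 for bile acid genes. Gstm3 and Cyp7a1 are members of the pericentral list, so these results are not separate from the pericentral one.

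The next lists were called at the preset correlation and not with an estimated one. Members are shared between lists: 14 of 26 urea cycle and 6 of 12 gluconeogenesis genes also stand in another list. Gldc, Fbp1 and G6pc are members of the periportal list, so both lists are not separate from the periportal result. Urea cycle and amino acid breakdown genes fell in 15 of 26 cases and rose in 5 (15 and 6 adjusted over the list alone; median -0.64, adjusted p = 1.38e-06; adjusted p = 0.103 with an estimated correlation), with Gldc, of the glycine cleavage system, 8.42-fold lower. Gluconeogenesis genes fell in 6 of 12 (6 adjusted over the list alone; median -0.39, adjusted p = 0.000827; adjusted p = 0.0789 with an estimated correlation), with Fbp1 2.17-fold and G6pc 2.28-fold lower. Glycolysis genes fell in 6 of 13 and rose in 1, with a median of -0.28 (adjusted p = 0.0271; adjusted p = 0.0789 with an estimated correlation). Fatty acid synthesis genes fell in 7 of 19 and rose in 2 (9 and 3 adjusted over the list alone; median -0.29, adjusted p = 0.00461; adjusted p = 0.118 with an estimated correlation), among them Fasn, fatty acid synthase, 2.18-fold lower and Pnpla3 at least 6.45-fold lower. Acute phase genes fell in 6 of 17 (7 adjusted over the list alone; median -0.42, adjusted p = 0.00158; adjusted p = 0.0771 with an estimated correlation), with Hamp, the iron regulator hepcidin, 2.49-fold lower. Immediate early and heat shock genes fell in 7 of 17 (8 down and 1 up adjusted over the list alone; median -0.31, adjusted p = 0.03; adjusted p = 0.344 with an estimated correlation), with Egr1 7.32-fold and Jun 2.62-fold lower. Female-biased liver genes rose in 16 of 38 and fell in 7 (19 and 8 adjusted over the list alone; median 0.46, adjusted p = 0.00171; adjusted p = 0.202 with an estimated correlation). Of 22 ribosomal protein genes limma called 0 (6 higher at an unadjusted p under 0.05), and the list median was 0.20 (adjusted p = 0.00629; adjusted p = 0.202 with an estimated correlation), but 0.02 with quantile normalization (adjusted p = 0.622).

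The other 17 lists were not called for zone in both sexes. Their medians were -0.68 for neutrophil, -0.39 for red blood cell, -0.24 for stellate cell, -0.22 for interferon response, and -0.15 each for Kupffer cell and macrophage, pancreas and gut, and cell cycle. ER stress and the growth hormone and steroid receptor axis had medians of -0.13, complement and coagulation of -0.09, oxidative phosphorylation of 0.04, hypoxia response of 0.09, cholesterol synthesis of 0.12, X chromosome escape and Y chromosome of 0.15, circadian clock of 0.16 and endothelium of 0.19. Adjusted p-values of these lists ranged from 0.229 to 0.899.

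**Figure D1:**
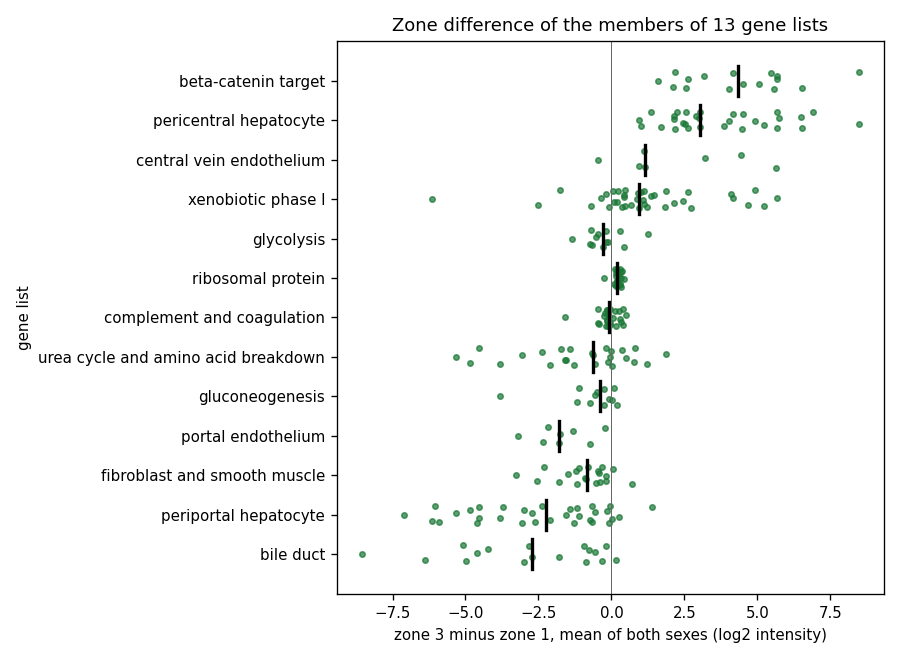
Zone 3 minus zone 1 log2 differences, as the mean of both sexes, for the tested members of 13 gene lists; each point is a gene and each bar the median of its list. The medians run from 4.34 for beta-catenin targets to -2.71 for bile duct markers.

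In total, limma called 2529 genes for zone in both sexes, 1235 higher and 1294 lower in zone 3 (4514 at an unadjusted p under 0.05); centring on the median gave 1973 higher and 1080 lower, and no scaling 505 and 1924. With slide as a block 1158 genes were called, 1091 of them shared. Slc1a2 was then at 8.55, Glul at 5.61, Spp1 at -8.10 and Cyp2f2 at -5.70, and the medians of the pericentral, beta-catenin, periportal and bile duct lists were 3.07, 4.35, -2.00 and -2.44. Those of the lymphocyte and glycolysis lists were -0.13 and -0.43, and that of the immediate early list was -0.17 (adjusted p = 0.0677, no longer called). The median ratio to the unblocked estimates was 0.99, while the median standard error grew from 0.197 to 0.267, and Fasn, Hamp and Egr1 were no longer called. Normexp called 756 genes, 753 of them shared, and Pnpla3 and Jun were no longer called. Its medians were 1.87 for beta-catenin targets, -1.16 for bile duct, -1.03 for portal endothelium, -0.50 for fibroblast and 0.72 for central vein endothelium. The female-biased and ribosomal protein lists were at 0.27 and 0.12, and the lymphocyte and immediate early lists were at -0.08 and -0.11. Quantile normalization gave -0.60 for gluconeogenesis, -0.45 each for glycolysis and fatty acid synthesis, 0.26 for fatty acid oxidation and -0.20 for immediate early genes. Centring on the median gave -0.25 for gluconeogenesis, -0.15 each for glycolysis and fatty acid synthesis, -0.17 each for the lymphocyte and immediate early lists and 0.33 for ribosomal protein genes. The glycolysis list was not called with the replicate block.

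Zone was also compared within each sex, with 3 arrays per zone. In males Slc1a2 was at least 308-fold higher in zone 3 (log2 8.41), Oat 119-fold, Cyp2c37 102-fold and Cyp7a1 32.4-fold, while Spp1 was at least 261-fold and Cyp2f2 75.4-fold lower. Elovl3, a fatty acid elongase, was 20.9-fold higher in zone 3 of males (log2 4.39 ± 0.40). Pericentral genes rose in 30 of 30 cases in males with a median of 4.03 (3.77 at the bound), and the median of the beta-catenin targets was 4.46 (3.88 at the bound). Periportal genes fell in 22 of 32 cases (median -2.49), bile duct markers in 10 of 17 (-2.69) and portal endothelium markers in 7 of 8 (-1.92). Central vein endothelium markers rose in 5 of 7 cases with a median of 1.56, but adjusted p = 0.0617 with an estimated correlation.

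In females Slc1a2 was 376-fold higher in zone 3 (log2 8.56), Glul 64.4-fold (log2 6.01 ± 0.36), Oat 72.5-fold and the sulfotransferase Sult3a1 38.8-fold. Cyp4a14 was 31.6-fold and Slco1a1, an organic anion transporter, 11.8-fold higher in zone 3 of females, while Spp1 was at least 320-fold and Cyp2f2 66.5-fold lower. Pericentral genes rose in 27 of 30 cases with a median of 3.04, and beta-catenin targets had a median of 4.27 (3.77 at the bound). Periportal genes fell in 22 of 32 cases (median -2.05), bile duct markers in 10 of 17 (-2.31), portal endothelium markers in 6 of 8 (-1.55) and fibroblast markers in 7 of 20 (-0.62). In females the stellate cell list had a median of -0.35 and a mean of 0.17, and the red blood cell list of -0.30 and 0.17, so their sign depends on the measure.

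Limma called 1536 genes for zone in males, 760 higher and 776 lower (3741 unadjusted), and 1284 in females, 549 higher and 735 lower (3356 unadjusted). Centring on the median gave 1239 higher and 640 lower in males and 715 and 620 in females, and no scaling 200 and 1930 in females. With slide as a block 552 genes were called in males (526 shared) and 518 in females (441 shared). That fit takes the zone difference of males from slide 1, with 3 zone 3 arrays and 1 zone 1 array, and that of females from slide 3, with 1 and 3 arrays, so within-slide values are no separate support. The pericentral median was 3.76 within slide 1 and 2.99 within slide 3, the beta-catenin median 4.36 and 4.17, and the periportal median -2.38 and -1.80. With normexp the beta-catenin median was 1.57 in males and 2.36 in females, and that of bile duct -1.05 and -1.02. That of portal endothelium was -1.14 and -1.01, and that of central vein endothelium 0.91 in males.

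Across the 16270 genes, which are not independent, the male and female zone differences correlated at Pearson 0.715 and Spearman 0.462. Of 817 genes called in both sexes 815 had the same sign, 351 higher and 464 lower in zone 3, against 25.6 and 35.1 for independent lists. The correlation was 0.591 with slide as a block.

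**Figure D2:**
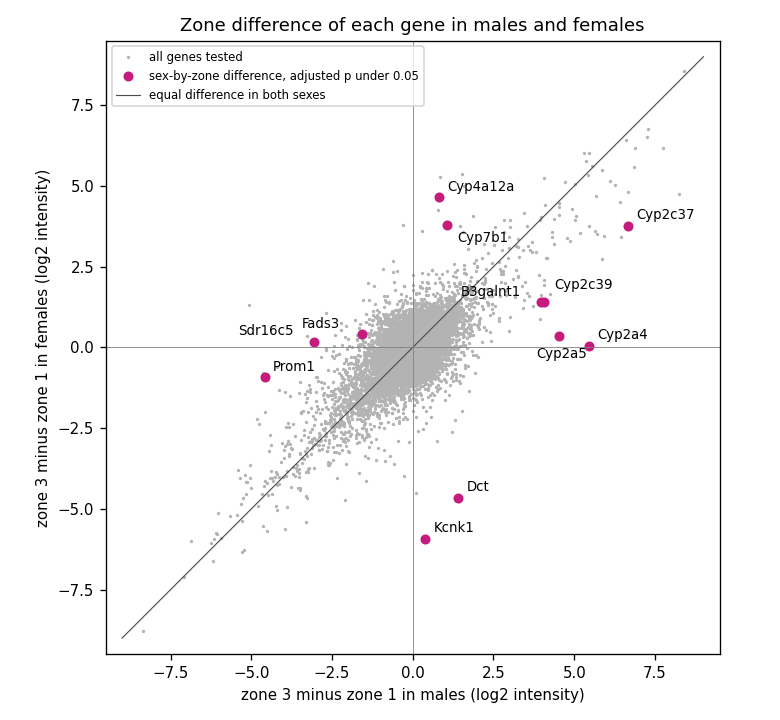
Zone 3 minus zone 1 log2 difference of each of the 16270 genes in males (x axis) and in females (y axis), with the line of equality. The 12 genes called for sex by zone are in magenta.

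The comparison of males with females in zone 1 asks which genes differ by sex around the portal tracts. Cyp2b9 was lower in males by -6.85 ± 0.34 (SE, n = 3 per sex; 115-fold, adjusted p = 4.2e-07), at 6.54 ± 0.21 (SD) in female zone 1. Also lower in males were the sulfotransferase Sult2a2 at least 60.6-fold and Cyp2a4, a steroid hydroxylase, by -5.31 ± 0.22 (39.8-fold). Higher in males were Cyp4a12a, a fatty acid hydroxylase, by 6.01 ± 0.27 (64.3-fold), Cyp7b1, an oxysterol hydroxylase, by 4.46 ± 0.22 and Gstp1 by 2.71 ± 0.20 (6.56-fold). Hsd3b5 was at least 56.9-fold higher in males and was measured on 1 of 3 female zone 1 arrays. Xist was 503-fold higher in females, and Ddx3y, on the Y chromosome, at least 44.9-fold higher in males.

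Of 38 female-biased liver genes 16 were lower and 1 was higher in males in zone 1 (29 and 2 adjusted over the list alone; median -1.37, or -1.19 at the bound, adjusted p = 3.39e-28). Male-biased genes were higher in 13 of 23 cases (17 adjusted over the list alone; median 1.82, adjusted p = 7.19e-31). All 4 Y chromosome genes were higher in males, with a median of 6.22 (4.71 at the bound), and the X chromosome escape list, with Xist called out of 5 members, had a median of -0.54. Fibroblast and smooth muscle markers had a median of -0.57 (0 of 20 called by limma, 6 unadjusted, 1 adjusted over the list alone; adjusted p = 0.00141), and these 5 lists were called with an estimated correlation as well.

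For markers of other cells in zone 1 few or no single genes were called. The lymphocyte list had a median of -0.57 (1 of 14 called; adjusted p = 0.00141, but adjusted p = 0.079 with an estimated correlation), Kupffer cell and macrophage markers of -0.55 (0 of 14 called by limma, 4 unadjusted; adjusted p = 0.0098, but adjusted p = 0.469 with an estimated correlation) and cell cycle genes of -0.79 (1 of 17 called, 8 adjusted over the list alone; adjusted p = 0.000259, but adjusted p = 0.121 with an estimated correlation). Birc5, a mitosis gene, was 4.05-fold lower in males. Endothelium (median -0.03, adjusted p = 0.923), portal endothelium (-0.11, adjusted p = 0.923) and stellate cell markers (-0.24, adjusted p = 0.626) were not called. Pericentral genes were lower in males in 6 of 30 cases (8 down and 1 up adjusted over the list alone; median -0.35, adjusted p = 0.00141, but adjusted p = 0.411 with an estimated correlation), among them Rgn at 3.97-fold and Cyp2c37 at 6.92-fold. The median of the conjugation list was 0.00 and its mean 0.13, with 3 members higher and 2 lower of 34 (adjusted p = 0.0163, but adjusted p = 0.328 with an estimated correlation).

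Limma called 125 genes for sex in zone 1, 64 higher and 61 lower in males (2314 unadjusted); centring on the median gave 89 and 51, and no scaling 30 and 111. The count was 68 without male zone 1 replicate 1, 72 without male zone 1 replicate 3, 74 without female zone 1 replicate 2 and 82 without female zone 1 replicate 3. No slide held both sexes of zone 1, and with slide as a block 21 genes were called, 18 of them shared, while the median ratio of the estimates was 0.98 and the median standard error grew from 0.279 to 0.5. In that fit Cyp2b9 stood at -7.31, Cyp2a4 at -4.74, Cyp4a12a at 5.74, Cyp7b1 at 4.37 and Gstp1 at 2.79, while Hsd3b5 at 6.07 was no longer called (adjusted p = 0.156), nor were Cyp2c37, Rgn and Birc5. The medians with slide as a block were -1.33 for the female-biased, 1.75 for the male-biased, -0.61 for the fibroblast, -1.26 for the Kupffer cell and -0.88 for the cell cycle list. They were -0.18 for the pericentral list, 0.16 for the conjugation list (adjusted p = 0.23, no longer called) and -0.18 for the lymphocyte list (adjusted p = 0.362, no longer called). With normexp the medians were 2.83 for the Y chromosome, -0.80 for the female-biased, -0.21 for the cell cycle and -0.19 for the pericentral list. The lymphocyte and conjugation lists turned to 0.04 and -0.11. Quantile normalization gave -0.02 for the conjugation list (adjusted p = 0.126, no longer called), centring on the median 0.13 for it and -0.21 for the pericentral list, and fry did not call the Kupffer cell list.

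The same comparison in zone 3 asks which genes differ by sex around the central veins. Sult3a1 was lower in males by -9.66 ± 0.62 (SE, n = 3 per sex; at least 372-fold, adjusted p = 8.25e-06) and was measured on 1 of 3 male arrays. Cyp2b9 was lower by -5.78 ± 0.34 (55.0-fold), Cyp2b13 53.2-fold and Cyp4a14 by -4.79 ± 0.45 (27.6-fold). Higher in males were Elovl3 by 4.14 ± 0.40 (17.6-fold), C6, a complement gene, 8.57-fold, Cyp4a12a 4.50-fold, Cyp7b1 3.36-fold and Gstp1 4.39-fold. Cish, a feedback inhibitor of cytokine signalling, was 5.94-fold higher in males, the repressor Bcl6 4.81-fold and the stress gene Gadd45g 12.5-fold, while Prlr, the prolactin receptor, was 2.70-fold lower.

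Of 38 female-biased genes 15 were lower in males in zone 3 (22 lower adjusted over the list alone; median -0.94, or -0.87 at the bound, adjusted p = 5.12e-17). Male-biased genes were higher in 10 of 23 cases (16 adjusted over the list alone; median 1.27, adjusted p = 5.87e-17). The Y chromosome list had a median of 6.99 (5.10 at the bound). Fibroblast and smooth muscle markers had a median of -0.60 (0 of 20 called by limma, 10 unadjusted, 7 adjusted over the list alone; adjusted p = 7.97e-05) and the lymphocyte list of -0.85 (1 of 14 called, 7 adjusted over the list alone; adjusted p = 8.03e-06), and these 5 lists were called with an estimated correlation as well. Kupffer cell markers had a median of -0.59 (adjusted p = 0.00698, but adjusted p = 0.396 with an estimated correlation), and cell cycle genes also of -0.59 (2 of 17 lower; adjusted p = 0.00386, but adjusted p = 0.225 with an estimated correlation), with Top2a, a DNA topoisomerase of dividing cells, at least 5.86-fold lower in males and measured on 2 of 3 male arrays. Endothelium markers had a median of -0.03 (adjusted p = 0.635). Conjugation genes were higher in males in 4 of 34 cases, with Gsta2 3.45-fold and Ugt2b35 2.85-fold (8 higher and 1 lower adjusted over the list alone; median 0.30, adjusted p = 4.22e-05, but adjusted p = 0.0529 with an estimated correlation).

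Limma called 181 genes for sex in zone 3, 88 higher and 93 lower in males (3315 unadjusted); centring on the median gave 180 and 66, and no scaling 65 and 42. The count was 89 without male zone 3 replicate 1, 83 without male zone 3 replicate 2, 101 without female zone 3 replicate 3 and 82 without both male zone 3 replicate 1 and female zone 3 replicate 3. With slide as a block 16 genes were called, 15 of them shared, with a median ratio of the estimates of 0.97. Cyp2b9 was then at -7.17, Sult3a1 at -8.99 and Cyp4a14 at -6.07, all still called, whereas Elovl3 at 3.67 (adjusted p = 0.256), Cyp7b1 at 1.99 (adjusted p = 0.329) and Gstp1 at 2.32 (adjusted p = 0.144) were not, nor were Cyp4a12a, C6, Cish, Bcl6, Gadd45g, Prlr, Gsta2, Ugt2b35 and Top2a. Normexp ended the calls of Cyp7b1, Cish, Gsta2, Ugt2b35 and Top2a. The medians with slide as a block were -1.82 for the female-biased, 1.18 for the male-biased, -0.53 for the fibroblast, -0.76 for the lymphocyte and -0.46 each for the Kupffer cell and cell cycle lists. With normexp they were 2.68 for the Y chromosome, 0.81 for the male-biased, -0.29 for the fibroblast, -0.37 for the Kupffer cell, -0.04 for the cell cycle and 0.11 for the conjugation list. The lymphocyte list turned to 0.01. The conjugation median was 0.14 with quantile normalization and 0.49 with centring on the median, and fry did not call the Kupffer cell list. Across genes, which are not independent, the sex differences in zone 1 and zone 3 correlated at Pearson 0.423 and Spearman 0.348, and the 59 genes called in both zones all had the same sign, 34 higher and 25 lower in males. Per the labels each mouse gave both zones, so deviations of a mouse can enter both differences, and their agreement is no independent replication.

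**Figure D3:**
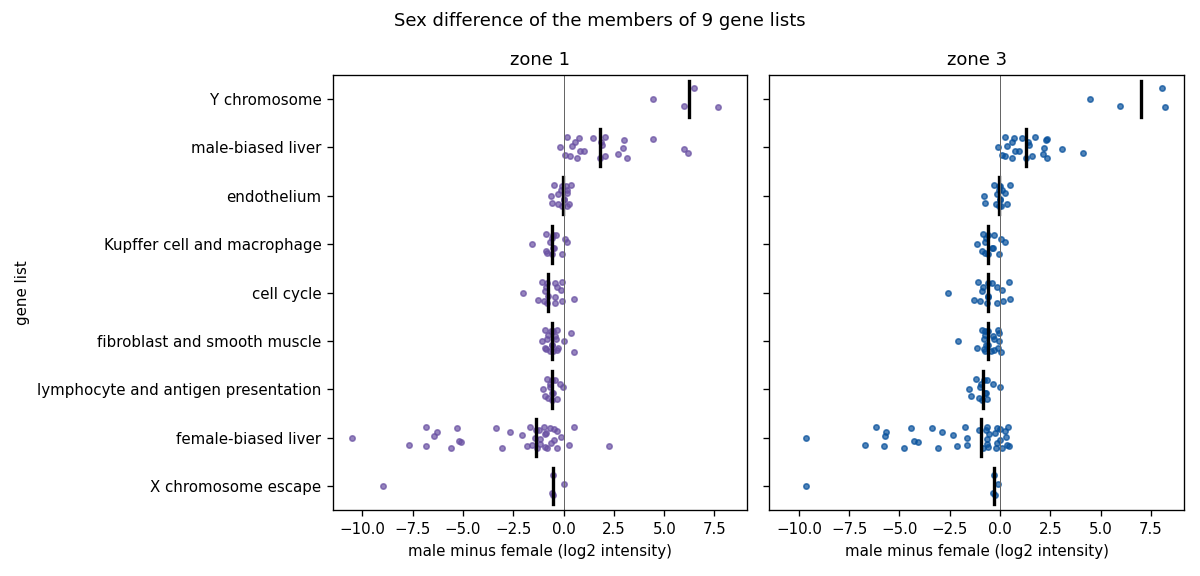
Male minus female log2 differences in zone 1 and in zone 3 for the tested members of 9 gene lists; each point is a gene and each bar the median of its list. The male-biased list has medians of 1.82 and 1.27, the female-biased list of -1.37 and -0.94.

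The last comparison, which the study's title names, asks in which genes the zone difference itself differs between the sexes. Limma called 12 genes (1328 unadjusted), 7 with a more positive and 5 with a more negative zone difference in males. Cyp2a4 was 43.9-fold higher in zone 3 than in zone 1 of males, while its zone difference in females was 0.05 (sex by zone log2 5.41 ± 0.31, SE, n = 3 per group, adjusted p = 1.62e-05). Its level was 5.70 ± 0.19 (SD) in female zone 1, 5.75 ± 0.24 in female zone 3, 5.84 ± 0.14 in male zone 3 and 0.38 ± 0.33 in male zone 1; its probe lies at 23210886 to 23211951 on chromosome 7 of mm7. Cyp2a5, a coumarin hydroxylase close to Cyp2a4 in sequence, rose 23.1-fold in males, with a zone difference of 0.35 in females (4.18 ± 0.42, adjusted p = 0.00168; chromosome 7, 23212159 to 23212218). The probes of Cyp2a4 and Cyp2a5 lie side by side in these coordinates, so both may read the same gene. Cyp2c37 rose 102-fold in males and 13.6-fold in females (2.91 ± 0.37, adjusted p = 0.0101), and Cyp2c39 16.8-fold and 2.65-fold (2.67 ± 0.25, adjusted p = 0.00132; chromosome 19).

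Another pair of genes was lower in zone 3 than in zone 1 of females. Kcnk1, a potassium channel, was at least 12.7-fold lower there, while its zone difference in males was 0.39 (6.31 ± 0.56, adjusted p = 0.00116; chromosome 8, 124617985 to 124618044). Its level was -0.58 ± 0.60 (SD) in female zone 1, and no female zone 3 array was well above background. With near-background values raised to the bound the sex by zone difference of Kcnk1 was 4.06 (adjusted p = 0.0113). Dct, dopachrome tautomerase of the melanin pathway, was 25.2-fold lower in zone 3 of females and had a zone difference of 1.40 in males (6.06 ± 0.68, adjusted p = 0.0039; chromosome 14, 112415582 to 112415642). B3galnt1, a glycosyltransferase, rose 15.6-fold in males and 2.64-fold in females (2.56 ± 0.38, adjusted p = 0.0375).

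The 5 genes with a more negative zone difference in males were Cyp4a12a, Cyp7b1, Prom1, Sdr16c5 and Fads3. Cyp4a12a rose 25.1-fold in zone 3 of females and had a zone difference of 0.81 in males (-3.84 ± 0.38, adjusted p = 0.00168; chromosome 4, 114704243 to 114705175), with levels of -0.98 in female zone 1 and 3.66 in female zone 3 against 5.02 and 5.83 in males. Cyp7b1 rose 13.7-fold in females and 2.09-fold in males (-2.71 ± 0.31, adjusted p = 0.00444; chromosome 3, 17798088 to 17798147). Prom1, which encodes the stem cell antigen prominin, was at least 4.93-fold lower in zone 3 of males, where no array was well above background, and had a zone difference of -0.93 in females (-3.66 ± 0.53, adjusted p = 0.0321). Sdr16c5, a retinol dehydrogenase, was well above background in male zone 1 and not in the other groups (-3.22 ± 0.33, adjusted p = 0.00168). With near-background values raised to the bound neither was called any longer, at -1.37 for Prom1 (adjusted p = 0.548) and -0.96 for Sdr16c5 (adjusted p = 0.521). Their sex by zone calls therefore rest on values near background. Fads3, of the fatty acid desaturase family, was 2.97-fold lower in zone 3 of males, with a zone difference of 0.40 in females (-1.97 ± 0.29, adjusted p = 0.0334).

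**Figure D4:**
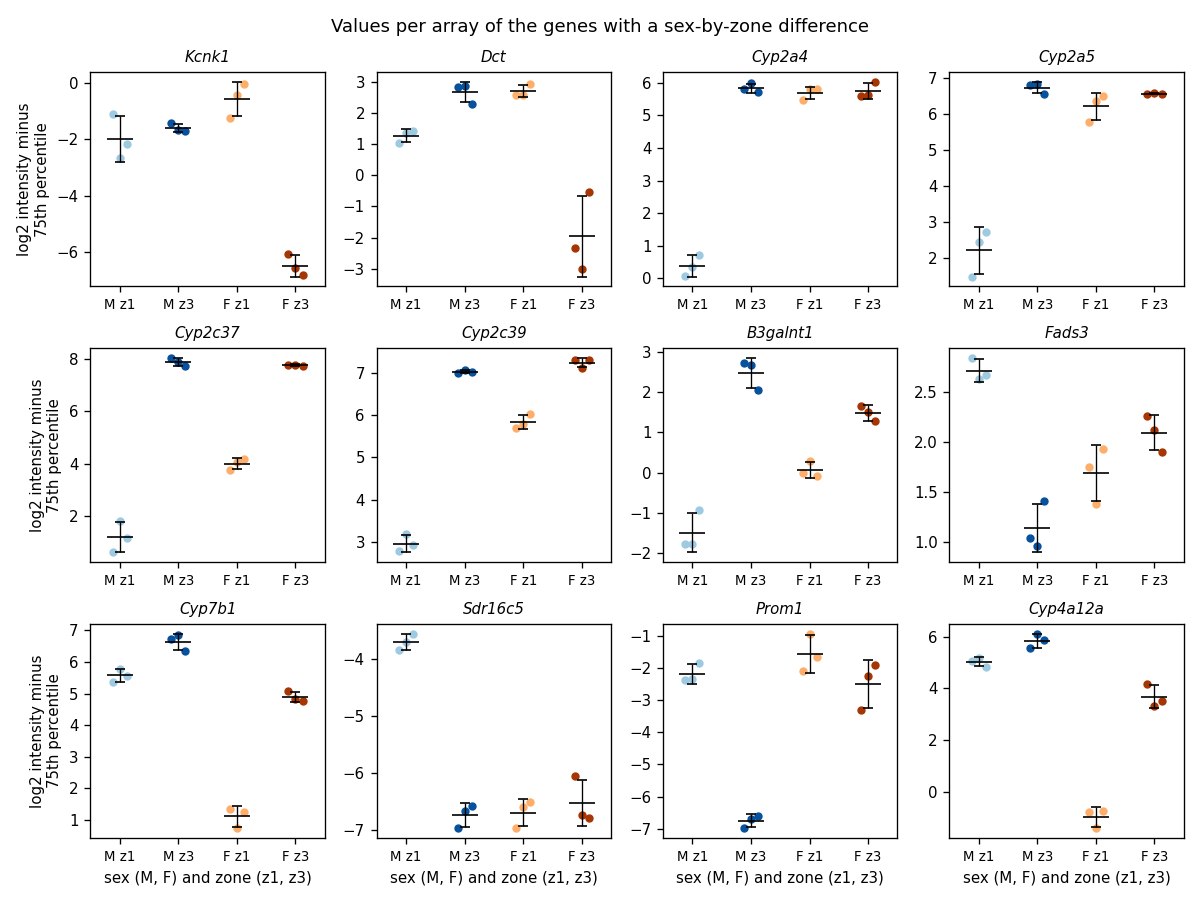
Level of each of the 12 genes called for sex by zone on each array, in log2 units relative to the array's 75th percentile, with the mean and SD of the 3 arrays per group. Cyp2a4 sits at 0.38 in male zone 1 and between 5.70 and 5.84 in the other groups.

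By list, the pericentral median for sex by zone was 0.49 (2 of 30 members more positive in males, 7 adjusted over the list alone; adjusted p = 7.2e-05, but adjusted p = 0.511 with an estimated correlation). The male-biased list had a median of -0.44 (2 of 23 more negative in males, 2 up and 5 down adjusted over the list alone; adjusted p = 0.00498, but adjusted p = 0.511 with an estimated correlation) and the xenobiotic list of 0.21 (3 of 39 more positive, 10 up and 2 down adjusted over the list alone; adjusted p = 0.00498, but adjusted p = 0.511 with an estimated correlation). Fatty acid oxidation genes had a median of -0.15 (0 of 25 called by limma, 4 unadjusted, 3 down adjusted over the list alone; adjusted p = 0.0163, but adjusted p = 0.519 with an estimated correlation). The members called in these lists are genes described above and no separate results. They were Cyp2a5 and Cyp2c37 in the pericentral list, the same and Cyp2c39 in the xenobiotic list, and Cyp4a12a and Cyp7b1 in the male-biased list. The female-biased list was not called (median 0.46, adjusted p = 0.197), with 1 member called in each direction over all genes and 12 up and 7 down adjusted over the list alone. The medians with slide as a block were 0.75, -0.20 (adjusted p = 0.0632, no longer called), 0.42 and -0.14 (adjusted p = 0.0549, no longer called) for the pericentral, male-biased, xenobiotic and fatty acid oxidation lists. That of the pericentral list with normexp was 0.25. Quantile normalization gave 0.15 for the xenobiotic list (adjusted p = 0.106, no longer called) and -0.28 for the fatty acid oxidation list, and fry called the xenobiotic list alone.

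With slide as a block Cyp2a4 (5.44, adjusted p = 0.00175), Cyp2a5 (4.93, adjusted p = 0.0087), Dct (4.87, adjusted p = 0.0142) and Kcnk1 (5.76, adjusted p = 0.0183) were still called, while Cyp2c37 (3.52, adjusted p = 0.0505), Cyp4a12a (-3.71, adjusted p = 0.153) and Cyp7b1 (-2.38, adjusted p = 0.262) were among the 8 that were not. Normexp ended the calls of 7 genes: Cyp2c37 (2.70, adjusted p = 0.0709), Cyp7b1 (-2.54, adjusted p = 0.258), Fads3 (-1.77, adjusted p = 0.261), and Kcnk1 (1.80), B3galnt1 (1.44), Prom1 (-0.36) and Sdr16c5 (-0.86), each of the last with adjusted p = 0.992. B3galnt1 and Fads3 also lost the call with the replicate block, no filter, the mean of kept probes and median centring. Prom1 lost it with no filter, the mean of kept probes and no scaling, Fads3 with no scaling, Cyp2c37 with the replicate block and Sdr16c5 with trend and robust estimation. Without both male zone 3 replicate 1 and female zone 3 replicate 3 the calls of Cyp2c37, B3galnt1, Prom1 and Fads3 ended. Cyp2a4, Cyp2a5 and Dct were called in every fit in which they were tested. Without scaling 16 genes were more positive and 4 more negative in males. B3galnt1 kept its call without male zone 3 replicate 3 or male zone 1 replicate 3 and lost it without any other array (log2 2.41 to 2.65, adjusted p = 0.0668 to 0.136). Prom1 kept it without female zone 3 replicate 1 or female zone 1 replicate 2 and lost it without any other array (-3.75 to -3.36, adjusted p = 0.0643 to 0.113), and Fads3 kept it without male zone 3 replicate 3, female zone 3 replicate 3 or female zone 1 replicate 3 and lost it without any other (-2.02 to -1.82, adjusted p = 0.0757 to 0.136).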

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

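In this part the tests of slide, of capture purity and of values raised to the background bound were chosen only after the result was seen.

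The zone difference differed between the sexes by the interaction term of the limma model in 12 genes. Given as the zone 3 minus zone 1 log2 difference in males minus that in females, the values were 6.31 for Kcnk1, 6.06 for Dct, 5.41 for Cyp2a4, 4.18 for Cyp2a5, 2.91 for Cyp2c37, 2.67 for Cyp2c39 and 2.56 for B3galnt1. They were -3.84 for Cyp4a12a, -3.66 for Prom1, -3.22 for Sdr16c5, -2.71 for Cyp7b1 and -1.97 for Fads3. Groups not well above background enter Kcnk1, Prom1 and Sdr16c5, and with near-background values raised to the bound these stood at 4.06 (adjusted p = 0.0113), -1.37 (adjusted p = 0.548) and -0.96 (adjusted p = 0.521), so that Prom1 and Sdr16c5 were no longer called. By the camera test on the same term, the pericentral hepatocyte list had a median of 0.49, the male-biased liver list of -0.44, the xenobiotic phase I list of 0.21 and the fatty acid oxidation list of -0.15, and with an estimated correlation 0 of these 4 lists were called by camera, with 3 lists of any kind at an unadjusted p under 0.05.

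The 12 genes were set against 3 technical explanations: slide, a ceiling of the signal in the brighter sex, and less pure captures in 1 sex. With slide as a block, which takes both zone differences within slides from 8 of the same 12 arrays, the median ratio to the unblocked estimates was 0.99 (0.80 to 1.21), which argues against slide as the whole cause, although only 4 genes were still called. A ceiling was argued against for the brighter genes, since each of the 12 had at least 11 other genes as bright that showed a called zone difference. For dim genes such as Kcnk1, Prom1 and Sdr16c5, with 718, 723 and 1174 such genes, the test could hardly have come out otherwise. Less pure captures in 1 sex would shrink the zone differences of that sex. As 8 genes had the larger zone difference in males and 4 in females, purity is argued against as the cause for all 12. Less pure female captures stay open as part of the cause for the 8. Cyp2a4 and Cyp2a5 showed little zone difference in females, where the pericentral median was 3.04 and the beta-catenin median 4.27. That argues against purity as the whole cause for Cyp2a4 and Cyp2a5. Several marker medians were larger in size in males: pericentral 4.03 against 3.04, periportal -2.49 against -2.05, bile duct -2.69 against -2.31 (but central vein endothelium 1.56 against 1.59). With normexp the pericentral medians were 2.94 in males and 2.61 in females, but the periportal medians were -1.78 and -2.02. Those of bile duct were then -1.05 and -1.02, and those of beta-catenin targets 1.57 and 2.36. The larger size in males thus depends on the processing except for the pericentral list. A difference in how females and males regulate these genes by zone is a candidate explanation, as a hypothesis found and tested on the same arrays. It is one for Cyp2a4, Cyp2a5 and Dct, which were called in every fit in which they were tested, and less so for the others. Cyp2c39 and Cyp4a12a stayed called with normexp (2.63 and -3.28) and lost the call with slide as a block (2.78 and -3.71). Normexp ended the calls of 7 genes. The estimate changed little for Cyp2c37 (2.70), Cyp7b1 (-2.54) and Fads3 (-1.77). It shrank for Kcnk1 (1.80), B3galnt1 (1.44), Prom1 (-0.36) and Sdr16c5 (-0.86), and the normexp offset shrinks differences of dim genes by construction. Signal shared between close copies stays open for the 5 genes of the Cyp2a, Cyp2c and Cyp4a families, and was not tested. The probes of Cyp2a4 and Cyp2a5 lie side by side on chromosome 7 in the coordinates of the files. Both may therefore read the same gene, and they are not to be counted as separate results.

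Of 100 splits of the 12 arrays into groups of the same sizes, 3 gave at least 12 genes for sex by zone, the real one included. These splits exchange arrays between the sexes and so mix the sex difference itself into the term, and they do not tell whether 12 genes could arise by chance. The highest other split gave 689 genes; it exchanges the sex of all zone 1 arrays and so measures the sex difference over both zones, a structure of the samples. The next gave 66 genes and exchanges replicates 2 and 3 of zone 3 between the sexes.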

How the results depend on the processing

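In this part leaving out both male zone 3 replicate 1 and female zone 3 replicate 3 and raising values to the background bound were chosen only after the data were seen, and so was the choice of which named genes to follow. Counts are of genes called, in the order zone in both sexes, zone in males, zone in females, sex in zone 1, sex in zone 3 and sex by zone. Quantile normalization, median centring, the filter for probes above background on all arrays, the mean of kept probes, slide as a random block and values raised to the background bound left all 6 counts within 1.5 times.

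Normexp gave 756, 268, 430, 51, 40 and 7 genes, and slide as a fixed block 1158, 552, 518, 21, 16 and 4, where fewer degrees of freedom and larger standard errors are part of its construction. The deposited values without scaling gave 2130 genes for zone in females, 107 for sex in zone 3 and 20 for sex by zone. Only the arrays of the comparison gave 827 for zone in females and 68 for sex in zone 3, with fewer arrays to estimate the spread. Array weights gave 221, 578 and 19 for sex in zone 1, sex in zone 3 and sex by zone. No filter gave 119 for sex in zone 3, trend and robust estimation 23 for sex by zone, and leaving out male zone 3 replicate 1 with female zone 3 replicate 3 gave 82 for sex in zone 3. Leaving out 1 array gave 2109 to 2690, 1050 to 1578, 896 to 1396, 68 to 135, 83 to 190 and 9 to 13 genes. Sex in zone 1 moved to 68 without male zone 1 replicate 1, 72 without male zone 1 replicate 3, 74 without female zone 1 replicate 2 and 82 without female zone 1 replicate 3. Sex in zone 3 moved to 89 without male zone 3 replicate 1, 83 without male zone 3 replicate 2 and 101 without female zone 3 replicate 3.

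Lists called fell with an estimated correlation from 21, 19, 20, 15, 18 and 4 to 12, 10, 12, 5, 5 and 0 (for sex by zone 3 lists at an unadjusted p). With slide as a block 9 lists were called for sex in zone 1, and with fry 1 for sex by zone. The correlation of zone differences between the sexes was 0.591 with slide as a block. The ribosomal protein list turned for zone in males under quantile normalization (adjusted p = 0.911), as did the fatty acid oxidation list for sex in zone 1 with slide as a block (adjusted p = 0.661).

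Values of single genes changed sign for Vil1 and for genes called for sex by zone. For Cyp2a4, zone in females became -0.07 with normexp, -0.08 with quantile normalization, -0.42 without scaling, -0.72 with the mean of kept probes, -0.03 with array weights, -0.09 without male zone 3 replicate 1 and female zone 3 replicate 3 and -0.09 to 0.13 without 1 array, negative without female zone 3 replicate 3 (-0.09) or female zone 1 replicate 1 (-0.06). Its sex difference in zone 3 became -0.11 with normexp, -0.08 with quantile normalization and -0.09 with the mean of kept probes. For Cyp2a5, sex in zone 3 became -0.13 with normexp and -0.01 with quantile normalization, and zone in females -0.12 without scaling. For Sdr16c5, sex in zone 3 became 0.41 with normexp, 0.01 with quantile normalization and -0.34 to 0.02 without 1 array (0.02 without female zone 3 replicate 1). Its zone difference in females became -0.30 without scaling, -0.09 with slide as a block and -0.06 to 0.30 without 1 array (-0.06 without female zone 3 replicate 1), and in both sexes 0.08 with normexp. Of the 12 sex by zone genes 5 were still called with normexp. Values raised to the background bound ended the sex by zone calls of Prom1 (-1.37, adjusted p = 0.548) and Sdr16c5 (-0.96, adjusted p = 0.521). Normexp gave 0.14 for Vil1 (zone in females), -0.18 for Cyp2c37 (sex in zone 3) and 0.08 for Prom1 (sex in zone 1). Slide as a block gave 0.09 for Cyp2c39 (sex in zone 3), 0.85 for Dct (sex in zone 1), -0.50 for Kcnk1 (zone in males) and 0.35 for Prom1 (sex in zone 1), and no scaling -0.07 for Fads3 (zone in females). Except where the construction is named above, the cause was not tested.

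The replicate block paired the zones by replicate number within sex. The data gave no sign that the numbers pair the arrays: the correlations of equal numbers after removal of group means were -0.03, 0.054 and -0.07 in males and 0.056, 0.059 and 0.013 in females, and the best partner had the same number for female 1 and male 2 alone. With it 2210, 1252 and 1066 genes were called for zone and 12 for sex by zone, 9 of them shared; as a random block 125 and 181 for sex. Spots not well above background (61.9% to 74.2% were well above it) limit the folds of dim genes.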

Other observations

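In this part the tests with slide as a block, of the other cells' markers against endothelium and other lists and of these markers within 1 zone were chosen only after the result was seen.

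Among genes of cells that line or surround the sinusoids, Reln, a stellate cell gene, was 3.35-fold higher in zone 3 as the mean of both sexes, while Pdgfrb, a receptor of mesenchymal cells, was 3.94-fold lower. The scavenger receptor gene Stab2 of the sinusoidal endothelium was 2.31-fold higher in zone 3, Kit at least 8.74-fold (measured on 2 of 3 female zone 1 arrays) and Thbd, which encodes thrombomodulin, 1.93-fold, a call that normexp ended. Egln3, an oxygen-sensing prolyl hydroxylase, was 2.83-fold higher in zone 3, Alas2, of haem synthesis, 2.60-fold and Lepr, the leptin receptor, 3.72-fold lower.

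In zone 1 the transcription factor gene Myc was 4.03-fold higher in males and Prlr 3.06-fold lower, and in zone 3 Myc was 4.44-fold higher in males, and with slide as a block none of these was called. Several lists not described above were called for sex at the preset correlation and not with an estimated one. In zone 1 these were complement and coagulation (median 0.14, adjusted p = 0.411 with an estimated correlation), cholesterol synthesis (0.12, adjusted p = 0.425 with an estimated correlation), oxidative phosphorylation (0.11, adjusted p = 0.565 with an estimated correlation), fatty acid oxidation (0.12, adjusted p = 0.411 with an estimated correlation) and immediate early and heat shock (0.32, adjusted p = 0.425 with an estimated correlation). In zone 3 oxidative phosphorylation had a median of 0.40 (adjusted p = 0.295 with an estimated correlation), ER stress of 0.39 (adjusted p = 0.332 with an estimated correlation), complement and coagulation of 0.24 (adjusted p = 0.257 with an estimated correlation), xenobiotic phase I of 0.23 (adjusted p = 0.313 with an estimated correlation), ribosomal protein of 0.18 and immediate early and heat shock of 0.15 (adjusted p = 0.384 with an estimated correlation for each). Negative medians in zone 3 were those of stellate cell at -0.72 (adjusted p = 0.125 with an estimated correlation), interferon response at -0.65 (adjusted p = 0.301 with an estimated correlation), portal endothelium at -0.42 (adjusted p = 0.153 with an estimated correlation) and X chromosome escape at -0.28 (adjusted p = 0.0529 with an estimated correlation). With normexp several of these medians turned: complement to -0.22 and -0.03 in zones 1 and 3, cholesterol synthesis to -0.09, oxidative phosphorylation to -0.19 and fatty acid oxidation to -0.12 in zone 1, and xenobiotic to -0.05, ribosomal protein to -0.08 and portal endothelium to 0.01 in zone 3. Other values with normexp were 0.15 for immediate early genes in zone 1, and in zone 3 0.11 for oxidative phosphorylation, 0.13 for ER stress, -0.29 for stellate cell, -0.10 for interferon response and -0.55 for X chromosome escape. Slide as a block gave 0.76 for cholesterol synthesis in zone 1 and, in zone 3, 0.35 for xenobiotic, 0.45 for immediate early and -0.65 for X chromosome escape. It ended the calls of oxidative phosphorylation (0.06, adjusted p = 0.625), fatty acid oxidation (0.01, adjusted p = 0.661), immediate early (0.59, adjusted p = 0.0905) and complement (0.11, adjusted p = 0.23) in zone 1. In zone 3 it ended those of stellate cell (-0.41, adjusted p = 0.0573), interferon response (-0.35, adjusted p = 0.0836), ER stress (0.38, adjusted p = 0.144) and ribosomal protein (0.18, adjusted p = 0.249). Quantile normalization ended the calls of complement (adjusted p = 0.126), oxidative phosphorylation (adjusted p = 0.129), fatty acid oxidation (adjusted p = 0.108) and immediate early genes (adjusted p = 0.0664) in zone 1. In zone 3 it ended those of xenobiotic (0.04, adjusted p = 0.63), complement (0.03, adjusted p = 0.244), portal endothelium (-0.40, adjusted p = 0.0891), immediate early (0.11, adjusted p = 0.0995), ER stress (0.20, adjusted p = 0.135) and ribosomal protein (0.02, adjusted p = 0.912), and gave 0.19 for oxidative phosphorylation and -0.45 for X chromosome escape. Centring on the median ended the calls of immediate early genes in both zones (0.34 in zone 3) and gave 0.25 for fatty acid oxidation, 0.25 for cholesterol synthesis, 0.27 for complement and 0.24 for oxidative phosphorylation in zone 1. In zone 3 it gave 0.41 for xenobiotic, 0.43 for complement, 0.36 for ribosomal protein, -0.23 for portal endothelium and -0.10 for X chromosome escape. Fry called none of the lists named here for zone 1, nor xenobiotic and ribosomal protein in zone 3.

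The fibroblast, lymphocyte, Kupffer cell and cell cycle lists were lower in males in both zones, with a pooled median of -0.60 over 65 members, of which 1 of 20 fibroblast genes and none of the others stand in another list, but with an estimated correlation the calls held only for fibroblast in both zones and lymphocyte in zone 3 (adjusted p = 0.079 for lymphocyte in zone 1, 0.469 and 0.396 for Kupffer cell and 0.121 and 0.225 for cell cycle). Of 10000 sets of genes matched on mean signal, 0 percent had a median as low. These lists were pooled after they were seen to be lower in males, so that rank and the intervals below are no separate support for the decrease. The middle 95% of the matched sets had medians of -0.11 to 0.10, so genes of the same signal were not lowered, which argues against a trend with intensity. With normexp the medians in zones 1 and 3 were 0.04 and 0.01 for lymphocyte and -0.21 and -0.04 for cell cycle. They were -0.45 and -0.29 for fibroblast and -0.50 and -0.37 for Kupffer cell. The treatment of the background therefore stays open for the lymphocyte and cell cycle lists. The mean of the members per array was lower in males by -0.56 in zone 1 (95% interval of a linear model on 3 arrays per sex -0.82 to -0.31) and by -0.62 in zone 3 (-0.89 to -0.34), and over both zones by -0.63 with slide as a block (-1 to -0.25, with both captures of a mouse taken as independent), which argues against slide as the whole cause for the pooled lists but not for the lymphocyte list in zone 1, whose median then was -0.18. Set against the mean of the endothelium markers, a list chosen after it was seen not to fall, the difference was -0.49 (-0.74 to -0.24) in zone 1, -0.55 (-0.74 to -0.35) in zone 3 and -0.52 over both, but all other lists of cells that are not hepatocytes together, 65 genes with the endothelium markers, were lower in males by -0.16 (-0.38 to 0.07) in zone 1 and -0.27 (-0.48 to -0.07) in zone 3, so a lower share of all other cell types in male captures stays open. More of some of these cells in female captures may remain, as may a sex difference in their gene expression, and neither was tested further.

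Genes that differ by sex were also zonal more often than other genes: of 671 genes called for the sex difference averaged over both zones, which takes both captures of a mouse as independent, without genes of the X and Y chromosomes, 212 (31.6%) were called for zone in both sexes. Matched draws gave 15.8% on mean signal (upper limit 18.6) and 13.7% on mean signal and residual spread (upper limit 16.2), and the real share was at percentile 100 of 10000 draws in each case, which argues against small estimated spread as the cause. With zone called in the fit with slide as a block 116 of the 671 (17.3%) were zonal, against 5.8% in draws matched on mean signal and residual spread (upper limit 7.6), again at percentile 100, which argues against slide as the whole cause. Of the 413 genes higher in females 34 were higher in zone 3 and 75 in zone 1 (27 and 31 with slide as a block), and of the 258 higher in males 80 and 23 (44 and 14). Only the zone calls were taken with slide as a block, and the 671 sex calls were not. The lean of genes higher in females towards zone 1 nearly vanished with the block, so slide stays open for that lean. The fibroblast list was lower in zone 3 (median -0.83) and in males (-0.57 in zone 1, -0.60 in zone 3). The Kupffer cell and cell cycle lists, also lower in males, were not called for zone (-0.15 each). A part of other cell types in the overlap of sex and zone was not tested and stays open. As a hypothesis, the zone difference of such genes was taken to be larger in the sex with the lower level: among 166 of them, measured on all arrays and not called for sex by zone, this held for 99, or 59.6% (95% exact interval 51.8 to 67.2, exact binomial p = 0.0159, with genes not independent), and in 104, or 62.7%, with slide as a block. A ceiling of the signal in the brighter sex was not tested for these genes and stays open.

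The counts of genes called were also taken for other splits of the arrays into groups of the same sizes. For zone in both sexes the real split gave 2529 genes and the highest other of 100 splits 42, with 1 split, the real one, as large. The count thus followed the zone labels, but 1 of 100 is the smallest share that these splits can give. Other splits mix the zones within a group, which widens the spread and lowers their counts. They also ignore that each mouse gave both zones. For the 3 against 3 comparisons only 10 splits exist, too few for a share under 0.05. The real and the highest other counts were 1536 and 0 for zone in males, 1284 and 1 for zone in females, 125 and 0 for sex in zone 1 and 181 and 4 for sex in zone 3, and in each case 1 of 10 splits, the real one, was as large.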
